A study of Mus musculus with 62 samples.

How the data were processed

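The study measured liver RNA of female mice 2, 4, 6 and 8 weeks after they received a melanoma line that causes cachexia (CAC), one that does not (NCAC) or a mock injection (Con). Per the labels' protocols, RNA was extracted with Trizol, libraries were made with a stranded TruSeq mRNA kit and sequenced on an Illumina NovaSeq instrument, and the libraries are biological replicates. Each was taken as 1 animal, with 5 per group and 7 in CAC at 8 weeks. The labels call the mice C57BL/6J, while the study's design text calls them NCI Ath/nude, and the extraction protocol mentions a lung carcinoma line that the groups do not include. Which applies could not be settled from the labels.

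The authors deposited 1 table of TPM for 47643 gene symbols in the 62 libraries, and each library was checked to sum to 1e+06. Per the submitters' processing notes the genome build was mm10. The aligner, the quantifier and the number of reads per library are not given in the sources used here, so neither depth nor counting error is known and no count model was used. Every column was matched to its group by its name (0 unmapped columns). Of the symbols 45090 matched the annotation used for gene positions and transcript lengths. No further filter by the authors was found in the table.

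Genes with at least 1 TPM in at least 5 libraries were tested, 12160 in all. The values log2(TPM + 1) were fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 12 groups over all 62 libraries and empirical Bayes moderation with a trend. Adjusted p-values are Benjamini-Hochberg within each comparison, and genes were called at adjusted p under 0.05 with no minimum fold. There were 15 comparisons: CAC with Con, NCAC with Con and CAC with NCAC at each week, the linear trend over the weeks of CAC minus Con and of NCAC minus Con (weights -3, -1, 1 and 3, given per 2 weeks), and Con at 8 with Con at 2 weeks. The sentinel genes, 16 chosen to be reported whatever their result, also had an exact permutation test of the group labels, whose smallest p is 0.00794 for 5 against 5. Figures were drawn with Python 3.11.15, NumPy 2.4.6 and matplotlib 3.10.9.

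Gene lists, 47 covering inflammation, metabolism, stress, cell types and other tissues, were written from general knowledge before the data were examined, as were the comparisons, tests, thresholds and the alternatives called planned in the closing section. Of these, 46 with at least 3 measured members were tested with camera at its preset correlation of 0.01, again with the correlation estimated for each list, and with the rotation test fry. The 1 list left out, for megakaryocytes and platelets, had 2 measured members. Members were also counted with p-values adjusted over the list alone. Some lists share members, such as Mt2 in the acute phase, glucocorticoid and iron lists and Fgl1 in the acute phase and hepatokine lists. Calls of such lists are therefore not independent. Because members of a list vary together, calls at the preset correlation are given with the value at the estimated one.

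Genes were named by a rule. Per comparison these were the 10 largest increases and decreases (5 for the trends and for Con at 8 against 2 weeks) among called genes with a mean of at least 5 TPM in a group. They also had to keep the sign of their difference when any 1 library was left out and to have a symbol that is not a predicted or clone name. To these were added the 2 to 4 members of each list described with the smallest p, and the 16 sentinel genes. A few genes that this rule names, 1 of them a sentinel gene, are not reported here. Near-identical paralogs such as the Mup, Saa, Cyp2c and immunoglobulin genes share reads, and the table does not say how these were assigned.

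The pipeline was tested on simulated data drawn from each gene's mean and residual spread, with 200 changed genes, 50 at each of 4 sizes. In the layout of CAC against Con at 8 weeks 60, 90, 100 and 100 percent of genes with a true log2 change of 0.5, 1, 2 and 3 were called, with 4.37 percent of the calls false. In that of 4 weeks 58, 78, 100 and 96 percent were called, with 4.60 percent false. Genes were drawn independently of each other, so these rates leave out genes that vary together and transcripts of other tissues in the real libraries.

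Alternatives tried were a pseudocount of 0.1, no filter, a filter at a mean of 5 TPM, median-of-ratios rescaling, quantile normalization, rescaling with the 20 highest genes removed, robust moderation, a fit within each week, a minimum log2 change of 1, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were leaving out 9 libraries with at least 100 TPM of Ctrb1 (pancreatic libraries), leaving out these and those with at least 10 TPM of Acta1 (12 other-tissue libraries), rescaling with the acute phase list removed, and 2 clock covariates. The covariates were the leading principal components of the clock genes' deviations from group means, holding 68.32 percent of the variance of 21 genes, and they do not remove clock differences between groups. Replicate numbers were not used to pair animals, since the labels name no pairing and same-number libraries of different arms were not regularly closer than others. Same-number correlations ran from -0.368 to 0.364, and their median was the higher in some weeks and pairs of arms (0.151 against -0.0468 for CAC and NCAC at 6 weeks) and the lower in others (-0.15 against 0.0573 for NCAC and Con at 8 weeks).

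Comparisons that share controls were set against 50 simulated groups with no effect and against controls split into 2 and 3 libraries. Correlations over libraries are Pearson and Spearman coefficients with permutation p-values from 1e+05 permutations, adjusted over the 4 relations tested, and repeated without the 2 farthest libraries. Group comparisons were repeated on 100 splits of the same libraries, the real one included. Where a result could be explained by composition or handling, a prediction was written and tested. No library was left out of the results as reported. Read-level quality, splicing and protein data were not analysed here.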

Results

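Liver transcriptomes were measured in female mice that received, at 2 months of age, a melanoma line that causes cachexia (CAC), a melanoma line that does not (NCAC) or a mock injection (Con). Livers were taken 2, 4, 6 and 8 weeks later, with 5 animals per arm and week except 7 for CAC at 8 weeks, 62 libraries in all. Values are TPM, so the sequencing depth of each library is unknown. Differences are on the log2 scale of TPM plus 1, with a standard error, and adjusted p-values are from limma over 12160 genes. TPM are given as means ± SD.

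At 8 weeks the acute phase response dominated the CAC liver. The serum amyloid transcripts Saa2 and Saa1, which encode apolipoproteins secreted in inflammation, rose by 9.10 ± 0.94 (adjusted p = 7.72e-11) and 7.78 ± 0.79 (adjusted p = 4.47e-11) in 7 CAC against 5 Con livers. Saa1 reached 30680 ± 13880 TPM, against 116.9 ± 36.2 in Con. Reads are shared between the 2 Saa copies, on chromosome 7 at 46740497 to 46742980 for Saa1 and 46751790 to 46754313 for Saa2 (mm10). Lcn2, a siderophore-binding protein made in inflammation (chromosome 2, 32384633 to 32388252), rose by 5.37 ± 0.53 (adjusted p = 1.71e-11), from 22.2 ± 3.75 to 1007 ± 290 TPM. For Saa1, Saa2 and Lcn2 every CAC library lay above every Con library (exact permutation p = 0.00126, adjusted p = 0.00289).

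Other transcripts of the same kind followed. Orm2, an acute phase plasma glycoprotein, rose by 4.72 ± 0.38 (adjusted p = 4.74e-14). The metallothioneins Mt2 and Mt1, zinc and copper binding proteins induced by glucocorticoids and cytokines, rose by 6.04 ± 0.58 (adjusted p = 1.05e-11) and 4.67 ± 0.50 (adjusted p = 2.4e-10). The chemokine transcripts Cxcl14 (3.73 ± 0.33, adjusted p = 1.29e-12) and Cxcl1 (3.67 ± 0.43, adjusted p = 1.98e-09) were higher, as was Prtn3, a neutrophil granule protease (5.11 ± 0.49, adjusted p = 8.01e-12). Sult1e1, which inactivates estrogens by sulfation, rose by 5.68 ± 0.76 (adjusted p = 7.63e-08).

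The 10 largest decreases at 8 weeks included 7 major urinary protein genes, Car3 and Hao2. Car3, a carbonic anhydrase abundant in hepatocytes (chromosome 3, 14863512 to 14872523), fell by 6.11 ± 0.57 (adjusted p = 4.82e-12), from 1098 to 47.8 TPM. Hao2, a peroxisomal hydroxyacid oxidase (chromosome 3, 98874521 to 98893239), fell by 4.76 ± 0.42 (adjusted p = 6.72e-13), from 70.8 to 3.61 TPM. Of the major urinary proteins, which carry pheromones, Mup12 was at -7.15 ± 1.25 (adjusted p = 1.13e-05), Mup14 at -7.03 ± 0.87 (adjusted p = 9.91e-09), Mup7 at -6.08 ± 0.85, Mup9 at -5.74 ± 0.72, Mup16 at -5.32 ± 0.84, Mup17 at -5.01 ± 0.74 and Mup3 at -4.72 ± 0.58. Copies of the Mup cluster share reads, so single members are not separable. Slco1a1, a sinusoidal organic anion uptake carrier, fell by 4.59 ± 0.77 (adjusted p = 6.11e-06).

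Of the hormones and metabolic genes reported whatever their result, Igfbp1, an insulin-repressed binding protein of insulin-like growth factors, rose by 2.61 (adjusted p = 0.00136), with wide spread at 138.7 ± 142.6 TPM in CAC. Pck1, the gluconeogenic carboxykinase, rose by 0.70 ± 0.27 (adjusted p = 0.0302). The stress hormones Fgf21 and Gdf15 fell by 1.51 ± 0.28 (adjusted p = 2.44e-05) and 0.89 ± 0.24 (adjusted p = 0.00269), Fgf21 from 3.87 to 0.527 TPM. Not called at 8 weeks were Igf1 (0.13, adjusted p = 0.414), Alb (0.02, adjusted p = 0.893), Hamp (-1.03 ± 0.75, adjusted p = 0.271, but 0.11 without CAC replicate 3), Cyp7a1 (-0.59, adjusted p = 0.509), Srebf1 (-0.60, adjusted p = 0.0576) and Angptl4 (-0.19, adjusted p = 0.663).

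In all, 714 genes were higher and 4291 lower in CAC than in Con at 8 weeks, 189 and 478 of them by at least 2-fold. The excess of lower genes depended on the scaling. The median of all tested genes was -0.21 as deposited, 0.01 after median-of-ratios rescaling, 0.01 after quantile normalization and -0.37 with the 20 highest genes removed. Higher and lower genes numbered 1613 and 1600 after median-of-ratios rescaling, 1782 and 1633 after quantile normalization, 1500 and 1540 with the acute phase list removed, and 494 and 6771 with the 20 highest genes removed. The counts of list members after median-of-ratios rescaling are therefore given below beside the deposited ones for the 8-week lists with called members. Leaving out any 1 library left 4214 to 5652 genes.

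**Figure D1:**
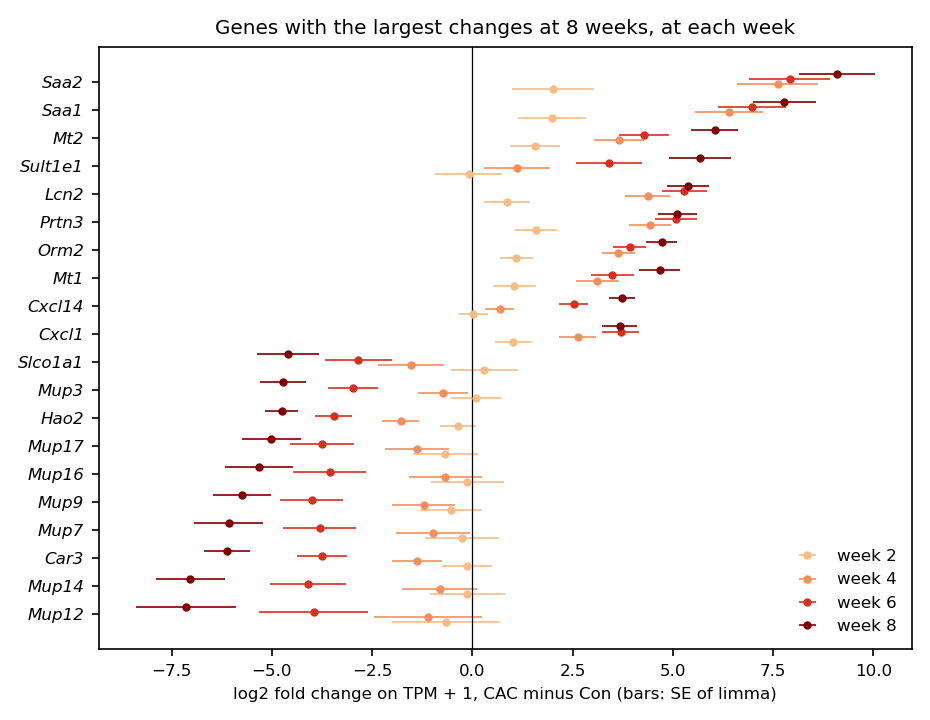
Genes with the largest called differences between CAC and Con at 8 weeks, from Saa2 at 9.10 to Mup12 at -7.15 on the log2 scale, with their values at the earlier weeks. Copies of the Saa and of the Mup genes share reads.

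The acute phase proteins rose nearly as a whole at 8 weeks. Of 31 measured members 29 were higher and 0 lower, 29 adjusted over the list alone and 29 after rescaling (median 2.07, camera adjusted p = 6.12e-68, adjusted p = 7.6e-06 with an estimated correlation). Lbp, which presents bacterial lipopolysaccharide, rose by 2.29 ± 0.17 (adjusted p = 1.79e-15), Orm1 by 2.66 ± 0.20 (adjusted p = 7.32e-15) and the haem scavenger Hpx by 2.07 ± 0.16. In the IL-6 and STAT3 response 13 of 20 members were higher and 1 lower, 14 and 1 adjusted over the list alone, 15 and 0 after rescaling (camera adjusted p = 9.61e-17, adjusted p = 7.6e-06 with an estimated correlation). Its feedback inhibitor Socs3 rose by 2.61 ± 0.27 (adjusted p = 5.54e-11), the oncostatin M receptor Osmr by 1.43 ± 0.15 and Il1r1 by 2.83 ± 0.34. Complement and coagulation had 16 of 36 members higher and 5 lower, also 16 and 5 adjusted over the list alone, 20 and 3 after rescaling (camera adjusted p = 2.3e-14, adjusted p = 0.0105 with an estimated correlation). Cpb2, a carboxypeptidase that slows clot lysis, rose by 1.39 ± 0.11 (adjusted p = 7.32e-15) and the kininogen Kng2 by 1.26 ± 0.11.

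The glucocorticoid response and iron and metal handling lists were called too. They share members with the acute phase list, Mt2 in both and Cp and Steap4 in the second, so they are partly the same genes. Of 23 glucocorticoid response genes 14 were higher and 1 lower, 15 and 1 adjusted over the list alone, 16 and 0 after rescaling (camera adjusted p = 2.3e-14, adjusted p = 0.0139 with an estimated correlation), with Mt2, Mt1, Sult1e1 and the tyrosine aminotransferase Tat (1.48 ± 0.30) leading. Iron and metal handling had 7 of 24 higher and 5 lower, the same 7 and 5 adjusted over the list alone, 8 and 3 after rescaling (camera adjusted p = 4.02e-05, adjusted p = 0.0139 with an estimated correlation). The ferroxidase Cp rose by 1.19 ± 0.14 (adjusted p = 6.19e-09) and the metalloreductase Steap4 by 1.83 ± 0.24.

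Lipid oxidation transcripts fell. In fatty acid oxidation and PPARA targets 32 of 38 members were lower and 0 higher, 32 adjusted over the list alone and 29 after median-of-ratios rescaling (camera adjusted p = 1.36e-13, adjusted p = 0.26 with an estimated correlation). The peroxisomal thiolase Acaa1b fell by 4.01 ± 0.48 (adjusted p = 3.64e-09), the fatty acid hydroxylase Cyp4a10 by 3.66 ± 0.44 and the fatty aldehyde dehydrogenase Aldh3a2 by 2.12 ± 0.27. In fatty acid and triglyceride synthesis 17 of 25 were lower and 0 higher, 18 adjusted over the list alone and 12 after rescaling (camera adjusted p = 0.00408, adjusted p = 0.466 with an estimated correlation). Me1, which supplies NADPH for lipid synthesis, fell by 1.92 ± 0.28 (adjusted p = 3.63e-07) and the elongase Elovl5 by 1.89. Cholesterol synthesis had 7 of 25 lower, 5 adjusted over the list alone and 3 after rescaling, and was not called as a list (camera adjusted p = 0.432), with the sterol desaturase Sc5d at -1.79 ± 0.27 (adjusted p = 7.64e-07).

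Lists of detoxification genes were called downward by camera at its preset correlation only. The drug metabolism P450 list had 23 of 42 lower and 3 higher, the same numbers adjusted over the list alone, 20 and 3 after rescaling (camera adjusted p = 0.00981, adjusted p = 0.427 with an estimated correlation). Cyp2a22 fell by 2.94 ± 0.33 (adjusted p = 8.74e-10), while Cyp3a13 rose by 1.91 ± 0.26. Among conjugation enzymes and NRF2 targets 29 of 41 were lower and 1 higher, 30 and 1 adjusted over the list alone, 22 and 4 after rescaling (camera adjusted p = 1.21e-05, adjusted p = 0.323 with an estimated correlation). The sulfotransferase Sult2a8 fell by 3.64 ± 0.41 (adjusted p = 6.82e-10), the glutathione transferase Gsta2 by 2.79 ± 0.32 and Ugt1a9 by 3.29 ± 0.40, whose first exons alone differ from those of its neighbours. Bile acid synthesis and transport had 16 of 25 lower and 2 higher, 17 and 2 adjusted over the list alone, 11 and 2 after rescaling (camera adjusted p = 0.0438, adjusted p = 0.466 with an estimated correlation). The bile acid hydroxylase Cyp8b1 fell by 2.38 ± 0.37 and the steroid dehydrogenase Akr1c6 by 1.53 ± 0.20 (adjusted p = 5.04e-08).

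The lists of growth hormone targets, female-biased genes and zonated genes were not called by camera at 8 weeks, though single members were. In growth hormone and STAT5 targets 13 of 22 were lower and 1 higher, as adjusted over the list alone (10 and 4 after rescaling, camera adjusted p = 0.138), with Mup3, Mup9 and Mup1 (-4.54) foremost. Female-biased genes had 8 of 20 lower and 2 higher, the same adjusted over the list alone (7 and 3 after rescaling, camera adjusted p = 0.369), with Hao2, Cyp4a10 and Cyp2b13 (-3.02) lower. Pericentral genes had 11 of 20 lower and 1 higher, 13 and 1 adjusted over the list alone, 8 and 1 after rescaling (camera adjusted p = 0.11). The Wnt antagonist Notum fell by 1.46 ± 0.17 (adjusted p = 3.58e-09). Periportal genes went both ways, 5 higher and 6 lower of 20 (8 and 6 after rescaling, camera adjusted p = 0.0921), with Arg1 up by 1.01 ± 0.18 and Etnppl at -2.03. Among hepatocyte markers 2 of 16 were higher and 3 lower, a balance that turned to 6 and 2 after rescaling (camera adjusted p = 0.0589). Fabp1, the liver fatty acid binding protein, fell by 2.74 ± 0.38 (adjusted p = 1.74e-07).

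Sugar and amino acid metabolism was mixed. Gluconeogenesis had 8 of 20 genes higher and 2 lower, also adjusted over the list alone, 12 and 1 after rescaling (camera adjusted p = 0.000219, adjusted p = 0.314 with an estimated correlation), though Fbp1 fell by 0.94 ± 0.17 (adjusted p = 2.3e-05). The serine dehydratase Sds rose by 1.37 ± 0.28. Glycolysis had 12 of 25 lower and 0 higher, as adjusted over the list alone (7 and 1 after rescaling, camera adjusted p = 0.18), with Eno1 at -0.89 ± 0.15 (adjusted p = 3.46e-06) and Pklr at -1.52. Amino acid catabolism and the urea cycle had 9 of 44 higher and 13 lower, 10 and 13 adjusted over the list alone, which turned to 16 and 4 after rescaling. That list was called upward (camera adjusted p = 0.0242, adjusted p = 0.617 with an estimated correlation) against a median of -0.06. Otc, the ornithine carbamoyltransferase, fell by 0.86 ± 0.11 (adjusted p = 4.42e-08) and Mat1a rose by 1.11 ± 0.19. Hepatokines had 7 of 29 higher and 8 lower, 9 and 6 after rescaling, and were called upward (camera adjusted p = 0.0339, adjusted p = 0.232 with an estimated correlation) despite a median of -0.19 and a mean of 0.07. Igfbp2 fell by 2.06 ± 0.27 (adjusted p = 3.41e-08) and Fgl1 rose by 1.10 ± 0.18.

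Respiratory chain and proteasome transcripts were lower by small amounts. Of 74 nuclear-encoded oxidative phosphorylation genes 70 were lower, 71 adjusted over the list alone but 18 after rescaling, with a median of -0.50 (camera adjusted p = 1.28e-14, adjusted p = 0.348 with an estimated correlation). The complex I subunit Ndufa10 fell by 0.59 ± 0.08 (adjusted p = 1.89e-08). Of 33 proteasome genes 33 were lower, 33 adjusted over the list alone but 14 after rescaling, with a median of -0.47 (camera adjusted p = 7.38e-10, adjusted p = 0.319 with an estimated correlation). The core subunit Psma6 fell by 0.59 ± 0.08 (adjusted p = 1.06e-07). Mitochondrially encoded transcripts had 4 of 13 lower, 4 adjusted over the list alone and 0 after rescaling (camera adjusted p = 0.999). Ribosomal protein genes had 5 of 78 lower, 0 adjusted over the list alone, and after rescaling 4 higher (camera adjusted p = 0.133), with Rpl35a at -0.41 (adjusted p = 0.00797).

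B and plasma cell markers had 13 of 13 lower, 13 adjusted over the list alone and 13 after rescaling (median -2.04, camera adjusted p = 1.5e-05, adjusted p = 0.348 with an estimated correlation), with the B-cell receptor chain Cd79b at -2.09 ± 0.33 (adjusted p = 2.58e-06). In Con at 8 weeks B and plasma cell markers had a mean log2 level of 4.735 and 4.689 in replicates 2 and 4, which held pancreatic transcripts, against at most 2.499 in the others. Kupffer cell markers had 9 of 16 lower, 10 adjusted over the list alone and 7 after rescaling (camera adjusted p = 0.088), including lysozyme Lyz2 (-1.61 ± 0.34). T and NK cell markers had 3 of 3 lower, 3 adjusted over the list alone and 2 after rescaling (camera adjusted p = 0.115), with Ccl5 at -1.71 and Gzma at -0.84, and had mean log2 levels of 2.653 and 2.164 in those same Con replicates 2 and 4 against at most 1.238 in the others. Erythroid markers had 6 of 9 lower, 6 adjusted over the list alone and 3 after rescaling (camera adjusted p = 0.115), with the carbonic anhydrase Car1 at -2.22 ± 0.26 (adjusted p = 1.65e-09). Neutrophil markers had 3 of 8 higher, 3 adjusted over the list alone and 3 after rescaling (camera adjusted p = 0.000526, adjusted p = 0.314 with an estimated correlation), namely Prtn3, Stfa2l1 (0.86) and Retnlg (0.77). Sinusoidal endothelial markers had 5 of 18 higher and 2 lower, as adjusted over the list alone, 5 and 1 after rescaling (camera adjusted p = 0.00893, adjusted p = 0.617 with an estimated correlation). Clec4g rose by 0.85, and Wnt2, a Wnt ligand of central vein endothelium, fell by 1.19 ± 0.17 (adjusted p = 1.55e-07).

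Stress and growth pathways had single strong members. The NF-kB list had 4 of 18 higher and 4 lower, the same adjusted over the list alone, 4 and 2 after rescaling (median -0.25, mean 0.06, camera upward adjusted p = 0.141), with Cxcl1 higher and Sod2 at -0.62 ± 0.11 (adjusted p = 1.21e-05). Interferon-stimulated genes had 7 of 37 lower, 4 adjusted over the list alone, and 2 lower and 1 higher after rescaling (camera adjusted p = 0.999), with Bst2 at -1.16 ± 0.23. MHC class I genes had 8 of 18 lower, 8 adjusted over the list alone, 1 lower and 1 higher after rescaling (camera adjusted p = 0.63), with B2m at -0.43 ± 0.10 (adjusted p = 0.000332) and H2-T23 at -0.59. The cell cycle list had 13 of 28 lower and 1 higher, as adjusted over the list alone (10 and 1 after rescaling, camera adjusted p = 0.0859), with Ccnd1 at -2.75 ± 0.43 (adjusted p = 1.38e-06) and Pcna at -0.61. p53 targets had 2 of 19 higher and 5 lower, also adjusted over the list alone, reversed to 5 and 1 after rescaling (camera adjusted p = 0.14). Btg2, an antiproliferative gene, rose by 1.94 ± 0.24 (adjusted p = 1.46e-08) and Cdkn1a by 2.17. Endoplasmic reticulum stress genes had 2 of 30 higher and 4 lower, 0 and 1 adjusted over the list alone, and 5 and 0 after rescaling (camera upward adjusted p = 0.0446, adjusted p = 0.633 with an estimated correlation, median -0.05), with Sec61b at -0.57 and Xbp1 at 0.36. ATF4 targets had 3 of 21 higher and 6 lower, as adjusted over the list alone (5 and 4 after rescaling, camera adjusted p = 0.239), with Ddit4 at 2.20 and Shmt2 at -0.80.

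Autophagy and lysosome genes had 3 of 33 higher and 11 lower, as adjusted over the list alone, but 8 and 6 after rescaling (camera adjusted p = 0.999), with Ctsl at 1.13 and Gabarapl1 at -0.92. Extracellular matrix and stellate cell markers had 6 of 27 higher and 6 lower, 6 and 9 adjusted over the list alone, 8 and 3 after rescaling, called upward (camera adjusted p = 0.0372, adjusted p = 0.633 with an estimated correlation) against a median of -0.26. The protease inhibitor Timp1 rose by 1.27 ± 0.21 and fibronectin Fn1 by 0.81. Heat shock and immediate early genes had 4 of 19 higher and 1 lower, 1 and 0 adjusted over the list alone, 5 and 0 after rescaling (camera adjusted p = 0.017, adjusted p = 0.348 with an estimated correlation), with Ier3 at 0.82 (adjusted p = 0.0037). The circadian clock list had 2 of 21 higher and 1 lower, 0 and 1 adjusted over the list alone, 2 and 1 after rescaling (camera adjusted p = 0.0174, adjusted p = 0.348 with an estimated correlation), with Nr1d1 at -2.32 ± 0.71 (adjusted p = 0.00705) and Per1 at 1.41. Cholangiocyte markers had 2 of 9 higher and 5 lower, 2 and 6 adjusted over the list alone, 2 and 1 after rescaling (camera adjusted p = 0.711), with Spp1 at 0.81 and Krt19 at -0.78. Adipocyte markers (0 of 11 called, 0 adjusted over the list alone, camera adjusted p = 0.999) and striated muscle markers (0 of 9, camera adjusted p = 0.999) gave no called gene by limma. Melanocyte markers had Dct higher (0.56, adjusted p = 0.0477) of 3 measured, 0 adjusted over the list alone and 1 after rescaling (camera adjusted p = 0.109). Pancreatic acinar markers had 14 of 14 lower, 14 adjusted over the list alone and 13 after rescaling (camera adjusted p = 0.0947), while Con replicates 2 and 4 held 1906 and 281.8 TPM of chymotrypsinogen Ctrb1 and so carried pancreatic transcripts.

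**Figure D2:**
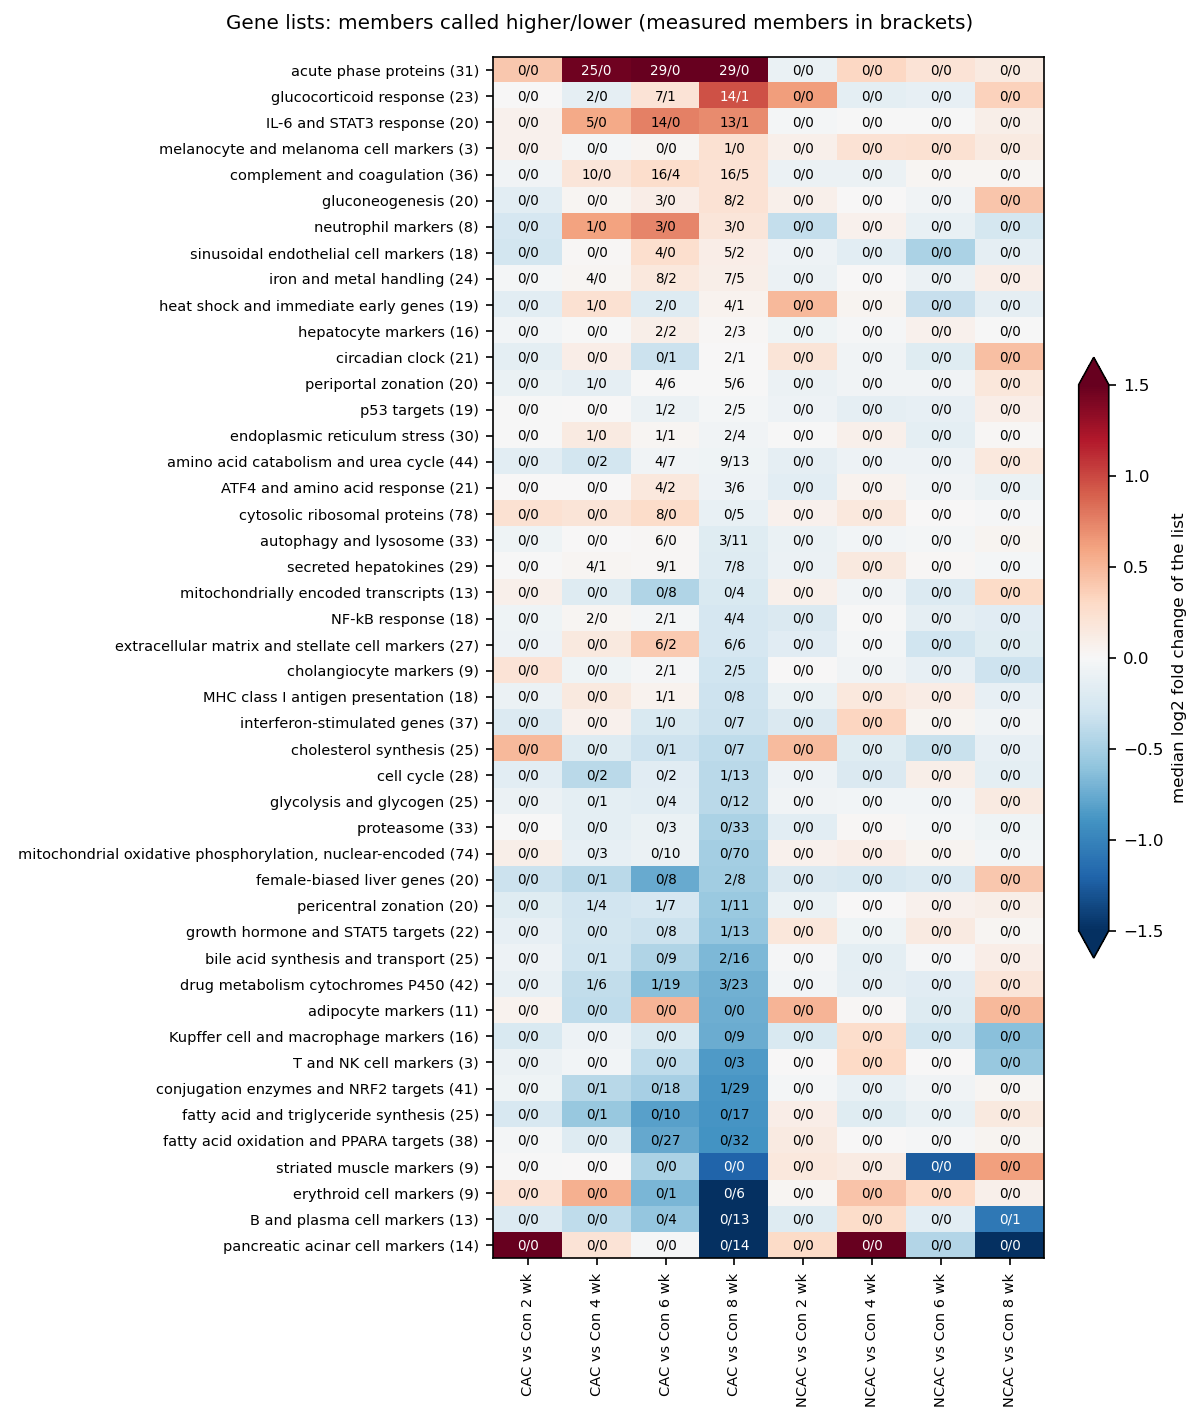
Median log2 difference of each gene list by comparison, with the acute phase proteins at 2.07 and B and plasma cell markers at -2.04 in CAC against Con at 8 weeks. The amino acid catabolism, ribosomal protein, mitochondrially encoded, MHC class I, hepatocyte, cholangiocyte, periportal, hepatokine, autophagy, endoplasmic reticulum stress, ATF4, extracellular matrix, NF-kB and p53 lists change their balance of higher and lower members at 8 weeks after median-of-ratios rescaling.

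At 6 weeks the same acute phase genes led. Saa2 rose by 7.91 ± 1.02 (adjusted p = 5.47e-08), Saa1 by 6.97 ± 0.85 (adjusted p = 1.83e-08), Lcn2 by 5.29 ± 0.57 (adjusted p = 5.93e-10) and Prtn3 by 5.08 ± 0.52 (adjusted p = 1.9e-10) in 5 CAC against 5 Con livers. Mt2 (4.29 ± 0.63), Orm2 (3.92 ± 0.41), Cxcl1 (3.70 ± 0.46), Mt1 (3.49 ± 0.54), Sult1e1 (3.41 ± 0.83, adjusted p = 0.00298) and the pentraxin Apcs (3.09 ± 0.36, adjusted p = 3.97e-09) were also higher. Igfbp1 rose by 2.70 (adjusted p = 0.00655). Lower were Mup14 (-4.10 ± 0.94, adjusted p = 0.00164), Mup9 (-4.01 ± 0.78), Mup12 (-3.96 ± 1.35), Mup7 (-3.81 ± 0.92), Mup17 (-3.75 ± 0.80), Mup1 (-3.72 ± 0.86), Mup16 (-3.56 ± 0.91) and the pseudogenes Mup-ps12 (-3.84 ± 0.43) and Mup-ps10 (-3.52 ± 0.35), which share reads. Car3 fell by 3.75 ± 0.62 (adjusted p = 1.29e-05).

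Counts at 6 weeks were 608 higher and 1254 lower, and the median of all genes was -0.12. Rescaling by median-of-ratios gave 1027 and 691, quantile normalization 1160 and 812, removal of the acute phase list 1208 and 453, and removal of the 20 highest genes 482 and 4043. Without CAC replicate 1, which held pancreatic and muscle transcripts, 906 genes were called, 434 higher and 472 lower. All other-tissue libraries left out gave 900 in all, and a fit within the week 2973.

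Among lists at 6 weeks, 29 of 31 acute phase proteins were higher and 0 lower, 29 adjusted over the list alone (camera adjusted p = 3.64e-65, adjusted p = 1.18e-05 with an estimated correlation), with Lbp at 2.12 ± 0.18 (adjusted p = 1.77e-12). The IL-6 and STAT3 response had 14 of 20 higher, 14 adjusted over the list alone (camera adjusted p = 9.78e-18, adjusted p = 4.17e-06 with an estimated correlation), with Socs3 at 2.86 ± 0.29. Complement and coagulation had 16 higher and 4 lower, 17 and 5 adjusted over the list alone (camera adjusted p = 4.13e-10, adjusted p = 0.0479 with an estimated correlation), with Cpb2 at 1.06 ± 0.12. Fatty acid oxidation had 27 of 38 lower and 0 higher, 30 adjusted over the list alone and 22 after rescaling (camera adjusted p = 4.02e-14, adjusted p = 0.221 with an estimated correlation), led by Aldh3a2 (-1.99 ± 0.29, adjusted p = 8.57e-07) and the peroxisomal bifunctional enzyme Ehhadh (-1.87 ± 0.28). The P450 list had 19 of 42 lower and 1 higher, 20 and 1 adjusted over the list alone (camera adjusted p = 4.5e-05, adjusted p = 0.221 with an estimated correlation), with Cyp2a22 at -2.97 ± 0.36. Conjugation enzymes had 18 of 41 lower, 20 lower and 1 higher adjusted over the list alone (camera adjusted p = 9.92e-05, adjusted p = 0.425 with an estimated correlation), with Ugt3a1 at -1.58 ± 0.23. Female-biased genes had 8 of 20 lower, 11 adjusted over the list alone (camera adjusted p = 0.0016, adjusted p = 0.278 with an estimated correlation). Ribosomal protein genes had 8 of 78 higher, 0 adjusted over the list alone and 29 after rescaling (camera adjusted p = 1.66e-17, adjusted p = 0.425 with an estimated correlation), and oxidative phosphorylation genes 10 of 74 lower, 9 adjusted over the list alone and 3 after rescaling (camera adjusted p = 0.626).

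At 4 weeks acute phase and inflammatory genes again led the called increases. Saa2 rose by 7.61 ± 1.02 (adjusted p = 4.24e-07) and Saa1 by 6.40 ± 0.85 (adjusted p = 4.24e-07), the latter to 9252 ± 8183 TPM against 89.0 ± 59.2 in Con (exact permutation p = 0.00794, the smallest that 5 against 5 can give). Prtn3 (4.42 ± 0.52), Lcn2 (4.37 ± 0.57), Mt2 (3.66 ± 0.63, adjusted p = 0.000101), Orm2 (3.64 ± 0.41), Mt1 (3.12 ± 0.54), Cxcl1 (2.63 ± 0.46), Apcs (2.51 ± 0.36) and Socs3 (2.46 ± 0.29, adjusted p = 5.55e-08) completed the 10 largest increases of called genes. Among the lower genes were Mup-ps12 (-2.08 ± 0.43, adjusted p = 0.0018), Hao2 (-1.79 ± 0.45, adjusted p = 0.0183), the P450 genes Cyp2c40 (-1.73 ± 0.46) and Cyp1a2 (-0.93 ± 0.24), Mup-ps10 (-1.58 ± 0.35) and the carboxylesterase Ces2c (-1.53 ± 0.33, adjusted p = 0.00256). Gsta2 (-1.29 ± 0.35), the carrier Slc22a30 (-0.99 ± 0.28) and the kinetochore gene Spc24 (-0.94 ± 0.25, adjusted p = 0.0262) were lower too. Reads of Cyp2c40 are shared with its Cyp2c neighbours.

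Counts at 4 weeks were 158 higher and 74 lower. Median-of-ratios rescaling gave 216 and 74, while removal of the 20 highest genes gave 156 and 247 and removal of the acute phase list 200 and 44. Without CAC replicate 2 the count was 135 and without Con replicate 5 it was 154, against 232 in all. Fitted within the week it was 99, with the other-tissue libraries left out 376 and with the pancreatic ones left out 364.

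At 4 weeks 25 of 31 acute phase proteins were higher, 29 adjusted over the list alone (camera adjusted p = 3.52e-80, adjusted p = 2.38e-06 with an estimated correlation), with haptoglobin Hp at 1.93 ± 0.23 (adjusted p = 6.32e-08) and Fgl1 at 1.57 ± 0.19. The IL-6 and STAT3 response had 5 of 20 higher, 9 adjusted over the list alone (camera adjusted p = 2.91e-15, adjusted p = 1.08e-05 with an estimated correlation), including Tnfrsf1a (0.71) and Stat3 itself (0.68). Complement and coagulation had 10 of 36 higher, 13 higher and 2 lower adjusted over the list alone (camera adjusted p = 8.59e-12, adjusted p = 0.03 with an estimated correlation), with the C1 inhibitor Serping1 at 0.77 ± 0.10. Hepatokines (4 higher and 1 lower of 29, 6 and 1 adjusted over the list alone, adjusted p = 0.0337 with an estimated correlation) and iron handling (4 of 24 higher, 7 higher and 2 lower adjusted over the list alone, adjusted p = 0.0432 with an estimated correlation) were called too, with Lect2 at -0.72 and the transferrin receptor Tfr2 at 0.48 ± 0.08. Cell cycle genes had 2 of 28 lower, 9 adjusted over the list alone (camera adjusted p = 8.07e-08, adjusted p = 0.37 with an estimated correlation).

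At 2 weeks no acute phase gene was called in the fit of all libraries. Fitted within week 2 alone, 2 of 31 acute phase proteins were higher in CAC than in Con and 7 of 31 higher than in NCAC, with 0 lower in either. Saa1 was at 1.98 ± 0.85 (adjusted p = 0.399), Saa2 at 2.01, Orm2 at 1.10 (adjusted p = 0.343) and Mt2 at 1.56 (adjusted p = 0.361) in CAC against Con. The 1 gene called by limma was the predicted gene Gm2000 (3.99, adjusted p = 0.00234), chosen here after its values were seen, which was also higher in Con at 8 than at 2 weeks (4.28). At an unadjusted p under 0.05 there were 1298 genes, and without Con replicate 3 the call count was 4. Acute phase proteins had 0 of 31 called and 2 higher adjusted over the list alone (median 0.40, camera adjusted p = 2.17e-13, adjusted p = 0.316 with an estimated correlation). Cholesterol synthesis had 8 of 25 higher adjusted over the list alone (median 0.49, camera adjusted p = 5.37e-13, adjusted p = 0.414 with an estimated correlation).

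**Figure D3:**
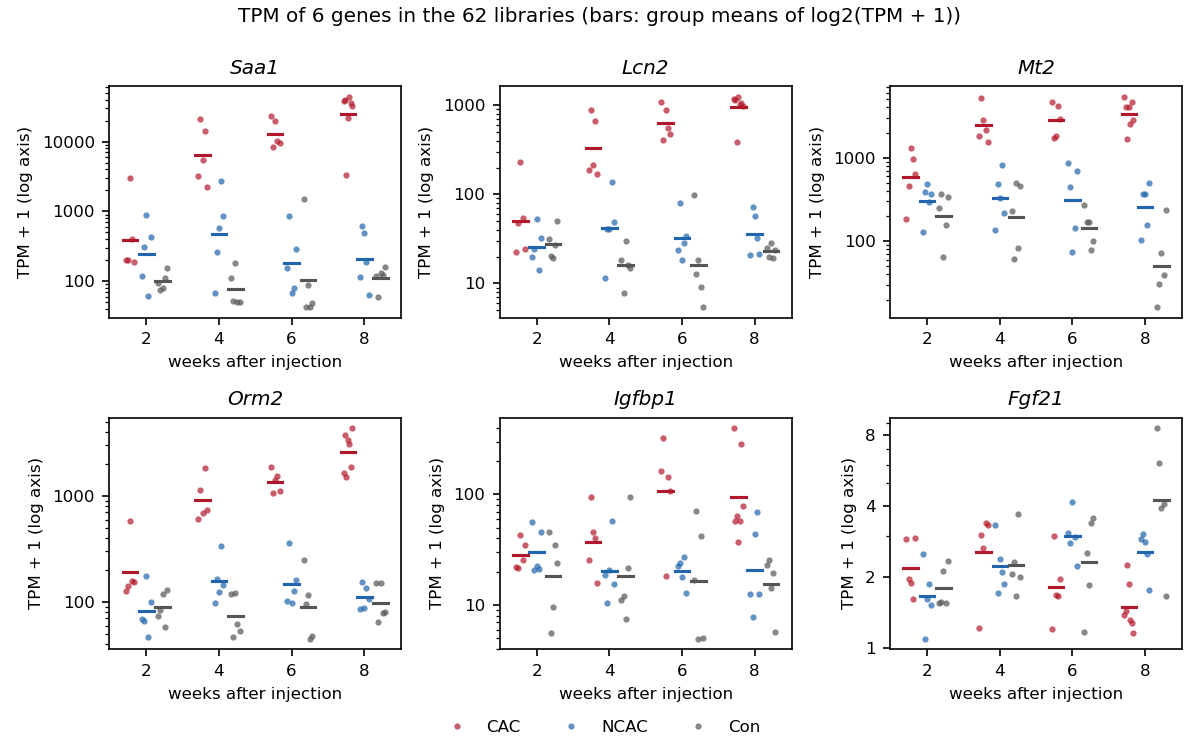
TPM per library of 6 of the genes reported whatever their result, with Saa1 at 30680 ± 13880 TPM in CAC and 116.9 ± 36.2 in Con at 8 weeks.

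Few genes were called in NCAC against Con in the fit of all libraries, which does not show that the livers were alike. Saa1 and Saa2 stood at 2.61 ± 0.85 and 3.51 ± 1.02 at 4 weeks (adjusted p = 0.617 for each). Mt2 stood at 2.32 ± 0.63 at 8 weeks (adjusted p = 0.0924). None was called over all genes. Adjusted over the list alone, 1 of 31 acute phase proteins was higher at 4 weeks (Saa2, adjusted p = 0.0344) and 1 at 8 weeks (Mt2, adjusted p = 0.0155). The list's camera adjusted p was 5.95e-10 at 4 weeks (0.523 with an estimated correlation) and 0.462 at 8 weeks. By limma 0 genes passed at 2, 4 and 6 weeks, with 1298, 934 and 1094 at an unadjusted p under 0.05. The 0 counts held under the other pseudocount, filters, scalings and robust moderation. Fitting the libraries of week 2 alone called 367 genes, weeks 4 and 6 alone 0. Clock covariates gave 295 genes at 2 and 2 at 6 weeks, and the replicate block 1 at 2 weeks. Without NCAC replicate 4 or Con replicate 1 at 2 weeks 1 gene was called, and 1 without NCAC replicate 5 at 6 weeks. Fry, a rotation test, called 0 lists in each of these weeks.

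At 8 weeks 3 genes were higher and 19 lower in NCAC than in Con, with immunoglobulin genes among the largest decreases. The heavy chain constant gene Ighg2c (chromosome 12, 113285325 to 113288932) was lower at -4.31 ± 0.76 (adjusted p = 0.00204), 0.0808 against 97.2 ± 141 TPM. Igkv3-7 (-3.38 ± 0.59, adjusted p = 0.00204), Ighv6-3 (-3.17 ± 0.59), Ighv5-17 (-2.48 ± 0.55), Igkv4-55 (-2.13 ± 0.42), Ighg2b (-2.12 ± 0.46), Ighv9-3 (-1.79) and Igkv12-41 (-1.76) followed, with reads shared between such segments. Dmbt1, a mucosal scavenger receptor, was at -2.99 ± 0.68 (adjusted p = 0.0383), and Cyth4, a leukocyte exchange factor, at -0.75 ± 0.16 (adjusted p = 0.0178). Higher were Sfxn1, a mitochondrial serine carrier (0.62 ± 0.13, adjusted p = 0.0105), and Extl1 (0.73 ± 0.17, adjusted p = 0.0472). These calls depended on single libraries, and Con replicates 2 and 4 held pancreatic transcripts. Left out in turn, Con replicates 1 to 4 gave 102, 1, 101 and 5 genes and NCAC replicates 1 to 5 gave 12, 8, 7, 10 and 72. With the libraries holding other tissues left out the count was 0, with 910 at an unadjusted p under 0.05, and fitted within the week it was 0, with 1028. Without a filter it was 182, with the stricter filter 2, with the pseudocount of 0.1 7, after quantile normalization 69, with clock covariates 79 and with the replicate block 9.

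Among lists of NCAC against Con, B and plasma cell markers at 8 weeks had 1 of 13 lower, 12 adjusted over the list alone (median -1.08, camera adjusted p = 2.5e-17, adjusted p = 0.152 with an estimated correlation). Kupffer cell markers had 0 of 16 called, 12 lower adjusted over the list alone (camera adjusted p = 9.67e-14, adjusted p = 0.152 with an estimated correlation). At 2 weeks cholesterol synthesis had 0 of 25 called, 8 higher adjusted over the list alone (median 0.47, camera adjusted p = 3e-13, adjusted p = 0.495 with an estimated correlation), with the sterol oxidase Msmo1 at 1.11 ± 0.24 (adjusted p = 0.154) and the squalene epoxidase Sqle at 0.96 ± 0.27 (adjusted p = 0.332). At 6 weeks sinusoidal endothelial markers had 11 of 18 lower adjusted over the list alone (median -0.48, camera adjusted p = 3.55e-09, adjusted p = 0.274 with an estimated correlation). At 4 weeks acinar markers had 14 of 14 higher adjusted over the list alone (median 3.34, camera adjusted p = 1.35e-22, adjusted p = 0.179 with an estimated correlation), with Ctrb1 at 186.6, 806.1 and 104.4 TPM in NCAC replicates 3, 4 and 5. The preset correlation called 13, 13, 17 and 21 lists at the 4 weeks, none of which was called with an estimated correlation.

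**Figure D4:**
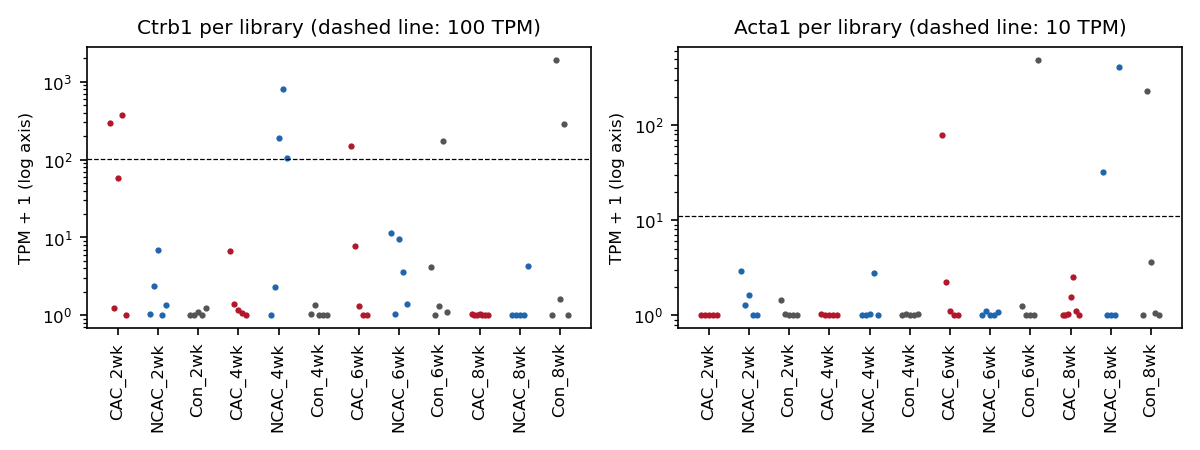
TPM per library of pancreatic and muscle transcripts, among them Ctrb1 at 1906 TPM and Acta1 at 225.7 TPM in replicate 2 of Con at 8 weeks.

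The 2 tumour arms were then compared directly, which tests whether the cachectic line differs from the non-cachectic one. At 4 weeks Saa2 was higher in CAC by 4.10 ± 1.02 (adjusted p = 0.0207), Saa1 by 3.78 ± 0.85 (adjusted p = 0.00696), Prtn3 by 3.30 ± 0.52 (adjusted p = 5.47e-05), and Lcn2 by 2.98 ± 0.57, and Mt2 was called too (adjusted p = 0.00413). Orm2 (2.56 ± 0.41), Mt1 (2.36 ± 0.54), Cxcl1 (2.21 ± 0.46), Apcs (2.06 ± 0.36) and the magnesium carrier Slc41a2 (2.07 ± 0.32, adjusted p = 4.49e-05) were higher too. Lower were the pancreatic elastase Cela1 (-2.42 ± 0.65, adjusted p = 0.0408), from the acinar transcripts in NCAC, and Cyp2c40 (-1.78 ± 0.46), Ces2c (-1.44 ± 0.33), Cyp1a2 (-0.99 ± 0.24), the carrier Slc25a45 (-0.83 ± 0.17) and Lect2 (-0.80 ± 0.17, adjusted p = 0.00302). The gulonolactone oxidase Gulo (-0.68 ± 0.15) and Gstt1 (-0.65 ± 0.18) were the smallest of these. Counts were 135 higher and 19 lower, 103 and 65 with the 20 highest genes removed. Acute phase proteins (24 of 31 higher, 27 higher and 1 lower adjusted over the list alone, adjusted p = 0.000124 with an estimated correlation), the IL-6 and STAT3 response (6 of 20, 10 adjusted over the list alone, adjusted p = 0.000174) and complement and coagulation (11 of 36, 19 adjusted over the list alone, adjusted p = 0.00446) were called either way. Counts were 101 in all without CAC replicate 2, 52 with the other-tissue libraries left out, 51 with the pancreatic ones left out and 65 fitted within the week.

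At 6 weeks Saa2 exceeded NCAC by 7.34 ± 1.02 (adjusted p = 3.15e-07), Saa1 by 6.13 ± 0.85, Prtn3 by 4.90 ± 0.52 (adjusted p = 1.09e-09), Sult1e1 by 4.74 ± 0.83 and Lcn2 by 4.31 ± 0.57. Isyna1, which makes inositol phosphate, was higher by 3.01 ± 0.32 (adjusted p = 6.78e-10). Lower were Mup12 (-5.45 ± 1.35), Mup7 (-5.13 ± 0.92), Mup16 (-5.04 ± 0.91), Mup9 (-5.00 ± 0.78, adjusted p = 4.23e-06) and Slco1a1 (-4.33 ± 0.83, adjusted p = 0.000147). Counts were 796 higher and 674 lower, 900 and 839 after median-of-ratios rescaling, 551 and 2146 with the 20 highest genes removed and 1712 and 410 without the acute phase list. Without CAC replicate 1 they came to 936 in all, and with the stricter filter to 957. Acute phase proteins (29 of 31 higher, 29 adjusted over the list alone, adjusted p = 0.000178 with an estimated correlation), the IL-6 and STAT3 response (13 of 20, 14 adjusted over the list alone, adjusted p = 6.16e-05) and iron handling (8 higher and 1 lower of 24, 9 and 1 adjusted over the list alone, adjusted p = 0.0273) were called either way. Sinusoidal endothelial markers had 12 of 18 higher, 12 adjusted over the list alone and 12 after rescaling (camera adjusted p = 2.91e-12, adjusted p = 0.137 with an estimated correlation), with Fcgr2b at 1.35 ± 0.19 (adjusted p = 5.1e-07) and Clec4g at 1.54 ± 0.22. Fatty acid oxidation had 25 of 38 lower, 31 adjusted over the list alone (camera adjusted p = 4.08e-18, adjusted p = 0.137 with an estimated correlation).

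At 8 weeks Saa2 was higher in CAC than in NCAC by 8.09 ± 0.94 (adjusted p = 2.26e-09), Saa1 by 6.87 ± 0.79, Orm2 by 4.55 ± 0.38 (adjusted p = 1.81e-13), Cxcl14 by 4.26 ± 0.33 (adjusted p = 3.27e-14) and Mt2 by 3.72 ± 0.58. Prtn3 (4.77 ± 0.49), Lcn2 (4.73 ± 0.53), Sult1e1 (4.28 ± 0.76) and Igfbp1 (2.20, adjusted p = 0.00544) were higher too, and Fgf21 was at -0.78 (adjusted p = 0.0173). Lower were Car3 (-6.05 ± 0.57, adjusted p = 7.53e-12), Hao2 (-4.92 ± 0.42, adjusted p = 2.26e-13), Cyp4a10 (-4.22 ± 0.44, adjusted p = 1.2e-10) and Mup9 (-5.12 ± 0.72). Gdf15 (-0.18, adjusted p = 0.557) and Pck1 (-0.01, adjusted p = 0.97) were not called. Counts were 619 higher and 5244 lower, but 1474 and 1568 after median-of-ratios rescaling, 1703 and 1611 after quantile normalization, 480 and 7210 with the 20 highest genes removed and 1181 and 1757 without the acute phase list. Acute phase proteins had 29 of 31 higher (camera adjusted p = 9.71e-70, adjusted p = 5.74e-06 with an estimated correlation) and fatty acid oxidation 35 of 38 lower, 36 adjusted over the list alone and 30 after rescaling (camera adjusted p = 9.07e-13, adjusted p = 0.205 with an estimated correlation). The IL-6 and STAT3, complement, hepatokine, glucocorticoid and iron lists were also called with an estimated correlation (adjusted p = 3.08e-06, 0.0052, 0.00882, 0.0496 and 0.0177). B and plasma cell markers had 4 of 13 lower, 4 adjusted over the list alone (camera adjusted p = 0.991). At 2 weeks 0 genes differed between the tumour arms by limma, with 1770 at an unadjusted p under 0.05. Without NCAC replicate 3 the count was 2, and 1 without CAC replicate 1 or NCAC replicate 5, but 935 fitted within the week and 566 with clock covariates.

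**Figure D5:**
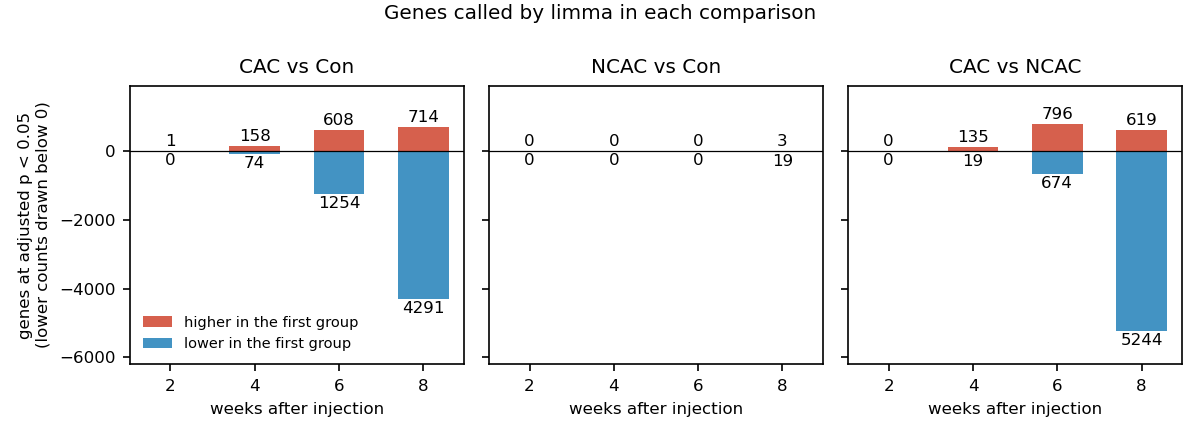
Genes higher and lower in each comparison at adjusted p under 0.05, drawn for the deposited TPM with 714 and 4291 for CAC against Con at 8 weeks. After median-of-ratios rescaling, not drawn, these were 1613 and 1600.

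The acute phase response of the CAC arm grew with time. Per 2 weeks the difference from Con grew by 2.16 ± 0.44 for Saa2 (adjusted p = 0.000509), 1.96 ± 0.36 for Sult1e1 (adjusted p = 0.000123), 1.80 ± 0.37 for Saa1 (adjusted p = 0.000533), 1.63 ± 0.43 for the steroid hydroxylase Cyp17a1 (adjusted p = 0.00703) and 1.44 ± 0.25 for Lcn2 (adjusted p = 4.95e-05). The share of all TPM taken by the acute phase list was 3.70 ± 1.24, 8.37 ± 3.79, 13.1 ± 3.47 and 18.6 ± 5.40 percent at 2, 4, 6 and 8 weeks in CAC, against 2.70 ± 0.192 percent in Con and 2.87 ± 0.627 percent in NCAC at 8 weeks. Mup14 (-2.40 ± 0.41, adjusted p = 4.46e-05) and Mup12 (-2.23 ± 0.58) declined per 2 weeks. The pancreatic genes Ctrb1 (-2.58 ± 0.70), Pnlip (-2.15 ± 0.58) and Clps (-2.15 ± 0.59) did so too, from CAC libraries at 2 weeks and Con libraries at 8 weeks that held them. In all 407 genes had a rising and 1499 a falling trend, 677 and 650 after median-of-ratios rescaling, 816 and 583 after quantile normalization and 324 and 3380 with the 20 highest genes removed. The total of 1906 became 850 without the other-tissue libraries, 903 without the pancreatic ones, 1200 with the acute phase list removed and 1194 with the replicate block. Acute phase proteins had 27 of 31 rising, 28 adjusted over the list alone (camera adjusted p = 6.2e-47, 0.000259 with an estimated correlation). Fatty acid oxidation had 30 of 38 falling, 32 adjusted over the list alone and 28 after rescaling (camera adjusted p = 1.13e-18, 0.116 with an estimated correlation).

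For NCAC no gene had a trend against Con by limma (0 genes, 1241 at an unadjusted p under 0.05). Without Con replicate 3 at 8 weeks 5 genes passed, without Con replicate 1 at 8 weeks 2, and 1 without any of Con replicate 1 at 2 weeks, Con replicate 1 at 4 weeks, NCAC replicate 4 or Con replicates 1, 2 or 5 at 6 weeks, or Con replicate 5 at 8 weeks. Fry called 0 lists (20 for CAC). B and plasma cell markers had 0 of 13 called, 2 falling adjusted over the list alone. Camera gave adjusted p = 1.71e-09 (0.405 with an estimated correlation).

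Called genes of the CAC arm were compared between weeks. Of genes called at both 6 and 8 weeks 405 were higher in both, against 35.7 by chance, 905 lower in both, against 443, and 2 opposite. At 4 and 6 weeks 145 were higher in both, against 7.9, and 56 lower, against 7.63. Across genes the differences from Con correlated between 6 and 8 weeks at r = 0.72 (rho 0.45), between 2 and 4 weeks at r = 0.39 (rho 0.39), between 2 and 6 weeks at r = 0.284 (rho 0.335) and between 2 and 8 weeks at r = 0.0329 (rho 0.106). The CAC and NCAC differences of 1 week share their controls, which alone gives a correlation. Their r was 0.299, 0.434, 0.225 and 0.439 at the 4 weeks, against 0.506, 0.485, 0.469 and 0.553 simulated for no effect. The covariance exceeded the simulated one by 0.00714, 0.015, 0.00649 and 0.0505, and with controls split between the arms the mean r was 0.103, 0.183, -0.0103 and 0.179.

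In mock-injected mice 33 genes were higher and 3 lower at 8 than at 2 weeks. Ighg2c was higher at 8 weeks by 4.14 ± 0.76 (adjusted p = 0.00259), Igkv3-7 by 3.31 ± 0.59 (adjusted p = 0.00235), Ighv6-3 by 3.22 ± 0.59, Dmbt1 by 3.21 ± 0.68 (adjusted p = 0.0139) and Ighv5-17 by 2.63 ± 0.55, with reads shared between immunoglobulin segments. Lower were the proline dehydrogenase Prodh (-0.70 ± 0.17, adjusted p = 0.0399), the folate enzyme Aldh1l1 (-0.68 ± 0.15, adjusted p = 0.0172) and the histidine-degrading Uroc1 (-0.50 ± 0.12, adjusted p = 0.0369). Amino acid catabolism had 2 of 44 lower, 8 adjusted over the list alone (median -0.38, camera adjusted p = 1.65e-22, adjusted p = 0.0204 with an estimated correlation). B and plasma cell markers had 2 of 13 higher, 13 adjusted over the list alone (camera adjusted p = 1.34e-16, adjusted p = 0.127 with an estimated correlation). The 36 calls became 0 with the other-tissue libraries left out, 0 with the replicate block, 1 fitted on the Con libraries alone, 2 with the stricter filter, 13 with the pseudocount of 0.1 and 291 without a filter. Leaving out Con replicates 1 to 5 of week 2 gave 23, 17, 23, 12 and 15 genes, and Con replicates 1 to 4 of week 8 gave 147, 7, 175 and 13.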

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

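Libraries were compared with their group for 15 genes, and a library was picked out when its gap to the nearest other exceeded the 95 percent limit of Dixon's test. For independent and normally distributed values chance picks out about 1 in 20 groups, or 9 of the 180 tests made, and 33 were picked out. The tests used TPM without a log, which are skewed, and several genes picked the same animal. The 33 against 9 is therefore no measure of an excess of unusual animals. In CAC at 2 weeks replicate 3 stood above its group in Saa1 (3050 TPM), Saa2 (1560), Lcn2 (231) and Orm2 (578), the acute phase genes that were called in CAC from 4 weeks on. In NCAC at 4 weeks replicate 4, which also held pancreatic transcripts, stood high in Saa1 (2760), Orm2 (334) and Igfbp1 (56.4). In NCAC at 6 weeks replicate 2 stood high in Saa1 (857), Lcn2 (79.2) and Orm2 (357). In Con at 6 weeks replicate 1 stood high in Saa1 (1490), Saa2 (1540) and Lcn2 (96.9). Saa2 was also high in NCAC at 2 weeks replicate 3 (744) and in Con at 2 weeks replicate 5 (55.2). Acute phase transcripts thus stood out in single animals of each arm.

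Other genes stood out in single libraries. Hamp, the iron hormone hepcidin, was high in Con at 2 weeks replicate 2 (4570 TPM), NCAC at 8 weeks replicate 3 (4900) and Con at 8 weeks replicate 4 (3280). Mt2 was high in Con at 8 weeks replicate 5 (234), which also stood high in Igf1 (197). Igf1 was high in CAC at 6 weeks replicate 5 (205). Gdf15 was high in CAC at 2 weeks replicate 1 (3.17), NCAC at 2 weeks replicate 1 (2.61) and NCAC at 6 weeks replicate 3 (2.43), and Igfbp1 in Con at 4 weeks replicate 5 (93.9). Pck1 was low in NCAC at 4 weeks replicate 5 (708). Cyp7a1 was high in CAC at 2 weeks replicate 2 (161) and low in CAC at 6 weeks replicate 3 (9.17), whose Srebf1 was high (123). Angptl4 was high in NCAC at 2 weeks replicate 1 (81.4) and Con at 6 weeks replicate 2 (78.6), and Alb in CAC at 4 weeks replicate 2 (102000). In CAC at 8 weeks replicate 3 stood low in Lcn2 (384, the next at 992).

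The linear trend of CAC minus Con in limma was called for 6 of these genes. Per 2 weeks it was 1.80 for Saa1, 2.16 for Saa2 and 1.44 for Lcn2 (adjusted p above). It was 1.11 for Orm2 (adjusted p = 2.05e-05), 1.41 for Mt2 (adjusted p = 0.000269) and -0.594 for Fgf21 (adjusted p = 0.0011).

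More genes were lower than higher in CAC against Con at 8 weeks, 4291 against 714, and the tests below were written before their results were seen. A loss of long transcripts through degraded RNA is argued against, since among 4 equal groups of genes by length the median of the longest exceeded that of the shortest by 0.172 log2, the opposite of such a loss. Transcripts of other tissues are argued against as the whole cause, since with those libraries left out 87.3 percent of called genes were still lower. The excess is consistent with the acute phase list taking a mean of 18.6 percent of all TPM, since with that list removed and the rest rescaled the median of all genes was 0.00403, with 1500 genes higher and 1540 lower. A fall of total mRNA other than acute phase transcripts per liver stays open, because TPM give shares only.

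For replicate 3 of CAC at 8 weeks, which lay between the other CAC libraries and the Con libraries, the test of a single mixing share was planned, and those of the acute phase list and of Hamp were chosen after earlier ones had been seen. On the axis from Con to CAC it stood at 0.397, with the other CAC libraries from 0.759 and Con and NCAC libraries up to 0.353, which left its origin undecided. An exchange with a Con or NCAC library of week 8 is argued against by the acute phase share. The highest among those was 3.82 percent against 18 in the lowest other CAC library (7.13 in replicate 3). A Con or NCAC library under a wrong label is argued against by 28 of 31 acute phase genes lying above all 40 such libraries. A CAC library of an earlier week under a wrong label was not tested, and the share in CAC at 4 weeks was 8.37 ± 3.79 percent. The planned test went with a mixture of a CAC and a Con library, as its 2 mixing shares differed by only -0.0174, but Hamp at 8.49 TPM, against at least 1890 in Con and 1010 in the other CAC libraries, is far below what any mixture of these could hold. An animal with a weaker or later tumour response was not tested. A response between Con and CAC would alone leave Hamp unexplained too, since it lay below both groups.

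Fitted alone, week 2 gave 721 genes in CAC against Con, 367 in NCAC against Con and 935 in CAC against NCAC, where the fit of all libraries gave 1, 0 and 0. The test of length in NCAC was planned and the others were chosen after the results were seen. In CAC the difference followed transcript length (rho -0.397, median length 1337.5 among higher and 5487 among lower genes against Con, and rho -0.35, 1929.5 and 5066 against NCAC), consistent with a technical difference in RNA handling between groups, while in NCAC it did not (rho 0.0161). A different time of day at sampling is argued against for CAC, where 0 clock genes were called against Con, and for NCAC it cannot be told apart from the arm, with 2 called against Con (Nr1d1 at -2.34 ± 0.365, adjusted p = 0.0197) and 4 between CAC and NCAC (Nr1d1 at 2.09, adjusted p = 0.0172). An early effect of either tumour stays open, as untested.

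The comparisons were repeated on 100 splits of their libraries into groups of the same sizes, the real one included. For CAC against Con, 6, 3, 1 and 1 splits gave as many genes as the real one at 2, 4, 6 and 8 weeks. At 6 and 8 weeks no other split drawn gave as many, which argues against chance. The 3 in 100 at 4 weeks, not adjusted over the comparisons, is weaker, and at 2 weeks chance is not excluded. The real counts were 1, 232, 1862 and 5005 and the highest others 2, 1078, 660 and 4869. The split with 4869 differed from the real one only in placing CAC replicates 3 and 5 with Con. The split with 1078 genes at 4 weeks set CAC replicates 1, 3 and 5 with Con replicates 1 and 2, several times the real count, which points to a structure of the samples. For NCAC against Con, 11 splits matched the real 22 at 8 weeks, so chance is not excluded. The 0 of the other weeks is no test, as any split matches it. The highest others were 1, 840, 2 and 536. The split with 840 joined the NCAC libraries holding pancreatic transcripts. That with 536 joined Con replicates 2 and 4 with NCAC replicates 1, 3 and 5. Both point to structure of the samples.

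For CAC against NCAC, 100, 21, 1 and 1 splits gave as many genes as the real 0, 154, 1470 and 5863, with 1, 2417, 388 and 3914 the highest others. Chance is argued against at 6 and 8 weeks, not at 4. The 0 at 2 weeks is no test. The 2417 genes with CAC replicates 1, 3 and 5 beside NCAC replicates 2 and 5 point to sample structure. The splits argue against chance for the trend of CAC (1 split, 1906 genes, highest other 916) and Con at 8 against 2 weeks (1 split, 36 genes, highest other 24). The 0 genes of the NCAC trend are no test (highest other 58). Fitted within week 2, the 721, 367 and 935 genes were each matched by 1 split, the real one, with 27, 60 and 535 the highest others.

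The number of lists called at the preset correlation was a poor measure, and its splits for CAC and NCAC against Con at 8 weeks were added after the results were seen. For CAC against Con 74, 4, 18 and 28 splits called as many lists as the real 11, 24, 23 and 22, the highest others being 19, 26, 29 and 30. For NCAC against Con 36, 58, 47 and 12 splits matched the real 13, 13, 17 and 21, with highest others of 20, 24, 23 and 25. For CAC against NCAC 67, 14, 19 and 12 splits matched 11, 21, 25 and 25, with highest others of 21, 25, 30 and 29. The lowest, 4 for CAC against Con at 4 weeks, is weak and unadjusted.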

How the results depend on the processing

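Of the alternatives, those leaving out libraries with other tissues or pancreatic transcripts, removing the acute phase list and adding clock covariates were chosen after seeing the data, and the rest were planned. Counts of genes are of those higher and lower together, beside reported counts of 1, 232, 1862 and 5005 for CAC with Con at 2, 4, 6 and 8 weeks, 0, 0, 0 and 22 for NCAC with Con, 0, 154, 1470 and 5863 for CAC with NCAC, 1906 and 0 for the trends of CAC and NCAC and 36 for Con at 8 with 2 weeks. Named below is each count that moved by more than 1.5 times. Except where a library or list was removed, the cause was not tested.

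Scaling moved the largest counts. With the 20 highest genes removed CAC with Con gave 403 at 4 and 4525 at 6 weeks, CAC with NCAC 2697 at 6 weeks and the CAC trend 3704. Median-of-ratios rescaling gave 5 and 3213 for CAC with Con at 2 and 8 weeks and 3042 for CAC with NCAC at 8. Quantile normalization gave 8 for CAC with Con at 2 weeks, 3314 for CAC with NCAC at 8 and 69 for NCAC with Con at 8. Removing the acute phase list gave 3 and 3040 for CAC with Con at 2 and 8 weeks, 2938 for CAC with NCAC at 8 and 1200 for the CAC trend.

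Leaving out other-tissue libraries gave 0, 376 and 900 for CAC with Con at 2, 4 and 6 weeks, 52 for CAC with NCAC at 4, 850 for the CAC trend and 0 for both NCAC with Con at 8 and Con at 8 with 2 weeks. Leaving out the pancreatic ones gave 364 for CAC with Con and 51 for CAC with NCAC at 4 weeks, 903 for the CAC trend and 0 for the same 2 as before.

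Fitting within the week gave 721, 99 and 2973 for CAC with Con at 2, 4 and 6 weeks, 935 and 65 for CAC with NCAC at 2 and 4, 367 and 0 for NCAC with Con at 2 and 8, and, on Con libraries alone, 1 for Con at 8 with 2. Clock covariates gave 5 for CAC with Con at 2 weeks, 566 for CAC with NCAC at 2, 295, 2 and 79 for NCAC with Con at 2, 6 and 8, and 3 for the NCAC trend. A minimum log2 change of 1 gave 68, 325 and 667 for CAC with Con at 4, 6 and 8 weeks, 54, 349 and 586 for CAC with NCAC, 13 for NCAC with Con at 8 and 79 for the CAC trend. No filter gave 3 for CAC with Con at 2 weeks, 182 for NCAC with Con at 8 and 291 for Con at 8 with 2. The stricter filter gave 3 for CAC with Con at 2 weeks, 957 for CAC with NCAC at 6, 2 for NCAC with Con at 8 and 2 for Con at 8 with 2. The pseudocount of 0.1 gave 7 for NCAC with Con at 8 and 13 for Con at 8 with 2, and robust moderation 1 for the NCAC trend.

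With the replicate number within its week as a block, CAC with Con gave 1, 235, 1527 and 3876, NCAC with Con 1 at 2 and 9 at 8 weeks, the CAC trend 1194 and Con at 8 with 2 weeks 0. The labels do not say that the block pairs animals.

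Leaving out 1 library gave from 1 to 4, 135 to 288, 906 to 2035 and 4214 to 5652 for CAC with Con, 0 to 1, 0 to 0, 0 to 1 and 1 to 102 for NCAC with Con, and 0 to 2, 101 to 176, 936 to 1539 and 4927 to 6343 for CAC with NCAC. It gave 1548 to 2745 for the CAC trend, 0 to 5 for that of NCAC and 7 to 175 for Con at 8 with 2.

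The correlation of the CAC differences between 6 and 8 weeks was 0.45 by Spearman, against 0.72. Called lists reversed 4 times, all in NCAC with Con. With other-tissue libraries left out the median was -0.10 for oxidative phosphorylation and -0.27 for B and plasma cell markers at 4 weeks, and for the list cytosolic ribosomal proteins, NCAC vs Con 8 weeks, it was 0.0897. Leaving out 1 library moved that last median between -0.0939 (without Con replicate 1) and 0.0921 (without Con replicate 2, which held pancreatic transcripts). Of the remaining gene counts 323 stayed within 1.5 times, of counts of called lists 173 did and 23 fell below, of list results 3076 were the same, 644 weaker and 260 stronger, and of named genes 8963 were the same, 356 weaker, 29 stronger and 0 reversed.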

Other observations

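Fitted alone, week 2 showed small shifts in both tumour arms that the fit of all libraries did not call. In CAC against Con 167 genes were higher and 554 lower, led by Wdfy2, an endosomal adaptor, at -0.98 ± 0.115 (adjusted p = 0.00378), Zbed6 at -1.22, Mtmr9 at -0.65 and the short transcript Tma7 at 0.46. Ribosomal protein genes had 19 of 78 higher, with Rpl39 at 0.56 and Rpl24 at 0.50, but genes higher in CAC were short (median length 1337.5 against 5487 among the lower, rho -0.397), as RNA handling could also cause. Cholesterol synthesis had 9 of 25 higher in CAC and 10 in NCAC against the same Con libraries. Sqle, the squalene epoxidase, was at 0.74 ± 0.19 (adjusted p = 0.0376) in CAC and 0.96 (adjusted p = 0.0276) in NCAC. Between the arms 0 of 25 were called (median -0.03), and as both share controls, the rise may come from low values in Con, which the 721 genes called for CAC and 367 for NCAC do not decide. Acute phase proteins had 2 of 31 higher in CAC than in Con, 7 of 31 higher in CAC than in NCAC (median 0.49) and 0 lower in either. That comparison with NCAC followed length too (rho -0.35, median 1929.5 among higher and 5066 among lower genes), and Saa1 stood at 3050 TPM in CAC replicate 3 alone, the next at 404. CAC replicates 1 and 4 held 292.2 and 376.8 TPM of the pancreatic Ctrb1, so an early response of the CAC arm stays open beside single libraries and a technical difference.

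Transcripts of T cells were low throughout. The T-cell receptor gene Trac was under 1 TPM in 61 of 62 libraries with a maximum of 2.22, Cd3e reached 0.932 at most and was 0 in 28 libraries, and Cd8a and Cd8b1 reached 0.463 and 0.408. B-cell transcripts were present, with Cd79a from 0.0689 to 21.8 TPM. Few T cells with B cells present may point to the athymic stock of the design text. The test, chosen after these values were seen, was H2-Ea-ps, which C57BL/6 mice do not express and which was at 1 TPM or more in 56 of 62 libraries (median 11.8), consistent with another stock than C57BL/6J. Nnt (14.4 to 43 TPM), a gene truncated in C57BL/6J, was expressed throughout, and Xist (20.8 to 148) in all libraries.

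Hamp, which restrains iron export, was far below its group in some libraries, lowest in CAC at 8 weeks replicate 3 at 8.49 TPM with Hbb-bs at 6170 and Alas2 at 65.1. Erythropoiesis lowers Hamp, so less Hamp where erythroid transcripts are higher was tested after these values were seen. Over 62 libraries Hamp and Alas2 had rho = -0.281 (permutation p = 0.048) and r = -0.53 (permutation p = 0.043), but r = -0.124 and rho = -0.206 without CAC at 8 weeks replicates 3 and 1. Hbb-bs and Hamp had r = -0.549 (permutation p = 0.01) and rho = -0.309 (permutation p = 0.029), and r = -0.174 and rho = -0.238 without replicates 3 and 4. All 4 permutation p-values stayed under 0.05 when adjusted over the 4 relations tested, at most 0.048. The r could therefore rest largely on those animals, while rho moved less, and the libraries do not decide it.

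Clock genes spread widely within groups. If animals were taken at different times of day, the oppositely phased Arntl and Dbp would oppose each other over libraries. This test was chosen after the spread was seen and gave rho = -0.699 and r = -0.769, each with a permutation p of 1e-05, the smallest that the permutations can give (adjusted p = 4e-05), and r = -0.692 without CAC at 6 weeks replicate 3 and Con at 2 weeks replicate 1. Sampling over the day is a candidate explanation of that spread, although disturbed feeding or sleep would give the same opposition and was not tested.

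Pancreatic acinar transcripts reached a limit of 100 TPM of Ctrb1, chosen after the values were seen, in 9 libraries, 3 of each arm (104.4 to 1906 TPM). Below that limit CAC at 2 weeks replicate 3 had 57.79 and NCAC at 6 weeks replicate 1 had 10.37, and muscle transcripts were present in others. The acinar and B-cell lists correlated over 62 libraries at r = 0.626 (permutation p = 0.00088) and rho = 0.466 (permutation p = 0.0013), with r = 0.551 without Con at 8 weeks replicate 2 and Con at 6 weeks replicate 4. Differences in immunoglobulin genes between NCAC and Con at 8 weeks and between the Con weeks could come in part from adjoining tissue such as pancreas with its lymph nodes. With other-tissue libraries left out, Ighg2c moved from -4.31 to -2.15 (adjusted p = 0.485) in NCAC against Con and from 4.14 to 1.93 (adjusted p = 0.444) between the Con weeks, and Igkv3-7 from -3.38 to -2.07 and from 3.31 to 2.13. The folds shrank but kept their direction, and with fewer libraries the loss of all calls does not tell the sources apart.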
